A study of Drosophila melanogaster with 4 samples.

How the data were processed

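The study profiled RPD3, a class I histone deacetylase of Drosophila melanogaster, by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in nuclei of larvae at the third instar, from the wild-type Oregon-R strain. The immunoprecipitations used the antibody labelled RPD3-Q3451. There were 4 samples, 2 ChIP and 2 Input, and the labels paired each Input with the ChIP sample of the same replicate number. Per the labels' protocols, homogenized tissue was crosslinked with formaldehyde, chromatin was released from the nuclei by SDS and sonication, and the chromatin bound by the antibody was collected on beads. The labels do not say whether the replicates came from separate collections of larvae, so the spread between them may be technical.

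Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Each deposited file is a list of regions called significantly enriched, here named clusters, with 1 score per cluster, per the file headers and columns on FlyBase release 5 of the genome. The tool that called the clusters, its thresholds, the way the 2 replicates were joined in the combined list and the scale of the authors' deposited score are not given in the sources used here. The Input samples served as the background of the list with the same replicate number, per the labels, and have no list of their own. The 3 lists are those of ChIP replicate 1, ChIP replicate 2 and the combined replicate set. No cluster was narrower than 1301 bp in either replicate list or narrower than 1001 bp in the combined list, so the lists had different minimum widths. The combined list also held 1 region named as depleted, which stayed out of all comparisons. All columns used were matched to a sample or to the combined set.

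The lists give no read counts, so sequencing depth is unknown and no interval for the signal at a cluster can be given. A position outside a cluster carries no value in these lists. Cluster scores were compared within the list that gives them, and between lists only by the correlation of the scores of overlapping clusters and by rank. Coordinates are 1-based positions of FlyBase release 5, as deposited. The gene table at hand describes release 6, so its coordinates were not set against the clusters. The planned comparisons with gene starts, annotated features, 17 gene lists and 6 sequence motifs were therefore not made, and clusters are named by position. Names of genes at these positions are not reported here.

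Clusters of the 2 replicates were compared by position, with an overlap of at least 1 bp, as the share of clusters that overlap and as the Jaccard index (bases covered in both lists divided by bases covered in either). Chance was set by 1000 circular shifts of 1 list within each chromosome, with a one-sided permutation p-value whose smallest possible value is 0.001. Scores of clusters that overlapped 1 to 1 were compared by Spearman's rho and Pearson's r across clusters, and scores of overlapping and non-overlapping clusters by their medians, with two-sided permutation tests of 100000 resamples. Clusters are not independent replicates, so these p-values describe the 2 lists and not the population of larvae. Shares of clusters carry Wilson 95% intervals, which cover counting error only. Values per chromosome arm are given per replicate with their mean and SD. An exact permutation test of 2 against 2 samples cannot pass a threshold of 0.05, since its smallest two-sided p is 0.333, and no test between samples was made.

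The overlap test was tested on simulated data made from the 5496 clusters of replicate 1. Of 20 pairs of independent random lists, 0 passed 0.05 with 100 shifts. These lists were placed uniformly along each chromosome and lack the uneven density of the real lists. The rate of false passes for lists with such density was therefore not measured. Of 20 pairs that shared 5% of their clusters, moved by up to 500 bp, with the rest placed at random, 20 passed, and so did 20 of 20 that shared 30% and 20 of 20 that shared 70%. The mean overlaps of 31.8%, 44.6% and 72.8% in these pairs equalled those of a separate count base by base. The clusters named below were chosen by a rule fixed before the data were examined, except those in neither replicate and those at the depleted region. The rule takes the 10 highest-scoring combined clusters that overlap both replicates, the 5 widest combined clusters, and the 3 highest-scoring clusters of each replicate that the other lacks. The alternatives were an overlap of at least 50% of the shorter cluster, the higher-scoring 50% of each list, the main arms alone, merging of clusters closer than 200 bp, counts in place of covered length, and for the arms the use of 1 replicate alone. Alternatives added after seeing the data were local shifts of 20 to 200 kb, a common minimum width, and arms without the 2 Mb next to the centromere, for scores on X the higher-scoring 50% and the overlapping clusters, for spacing the merging of clusters closer than 200 bp, and for cluster numbers, widths, covered length and spacing the use of 1 replicate alone. The windows of 500 kb and the spacing of clusters were also chosen after seeing the data, as were the comparison of scores between X and the autosomal arms and the split of clusters by score. Intervals for scores on X and for width ratios came from resampling 500 kb windows 1000 times (500 times within width deciles), with the windows of X and of the other sequences resampled apart. This separation was introduced after intervals from all windows resampled together had been seen. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.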

Results

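The data comprised RPD3 cluster lists from 2 ChIP samples of nuclei from larvae at the third instar, each called against its own Input sample, and a combined list. RPD3 is a histone deacetylase that acts in several corepressor complexes. The question the design addresses is where along the genome RPD3 was enriched over Input at this stage, and how far the 2 replicates placed it at the same positions. The read depth of the 4 samples is unknown from these lists.

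RPD3 enrichment was called as many clusters of a few kilobases, almost all on the 5 main chromosome arms. Replicate 1 held 5496 clusters and replicate 2 held 4991, a mean of 5244 ± 357 (SD, n = 2). Over all sequences they covered 19.1 Mb in replicate 1 and 16.0 Mb in replicate 2. Those on the arms X, 2L, 2R, 3L and 3R covered 15.9% and 13.2% of these arms. The median width was 2565 bp in replicate 1 and 2607 bp in replicate 2, and the 25th to 75th percentiles ran from 1964 to 4203 bp and from 1984 to 3783 bp. The share of clusters on the main arms was 98.0% in both replicates. Broad domains of at least 10000 bp were few in the replicates, with 153 in replicate 1 and 64 in replicate 2, where they held 10.2% and 4.88% of the covered sequence. The combined list held 321, with 18.0% of its covered sequence. Wider clusters had higher scores in both lists, with Spearman's rho of 0.74 in replicate 1 and 0.75 in replicate 2 across clusters.

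The replicates placed RPD3 at largely the same positions. Of the 5496 clusters of replicate 1, 4247 overlapped a cluster of replicate 2, which is 77.3% (Wilson 95% interval 76.1 to 78.4%). Of the 4991 clusters of replicate 2, 4562 overlapped a cluster of replicate 1, which is 91.4% (90.6 to 92.2%). Shifted lists overlapped at 23.5% and 26.3% on average, and none of the 1000 shifts reached the observed values (one-sided permutation p = 0.001 for each, the smallest the shifts can give). The Jaccard index of covered bases was 0.695, against 0.078 on average for shifted lists (permutation p = 0.001). No cluster had the same start and end in both lists. In the 3477 pairs of clusters that overlapped 1 to 1, the midpoints lay a median of 143 bp apart.

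Clusters found in both replicates had higher scores and were wider than those found in 1. In replicate 1 the median score was 0.950 for clusters that overlapped replicate 2 and 0.539 for the 1249 that did not, a difference of 0.411 (permutation test, p = 1e-05, the smallest the resamples can give). In replicate 2 the medians were 0.902 and 0.516 for the 429 that did not overlap, a difference of 0.386 (permutation test, p = 1e-05). Median widths were 3041 and 1728 bp in replicate 1, and 2742 and 1522 bp in replicate 2. Wider clusters had higher scores and can overlap more readily by position alone. Scores were not compared at matched widths, so score and width are not separated here. Among the replicate 1 clusters in the top 25% of scores, 1372 of 1373 overlapped replicate 2, and in the bottom 25% 642 of 1374 did. The matching counts for replicate 2 were 1242 of 1248 and 955 of 1248. Scores of the 1 to 1 pairs ranked alike, with Spearman's rho of 0.89 and Pearson's r of 0.90 across clusters (permutation p = 1e-05 for rho).

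**Figure D1:**
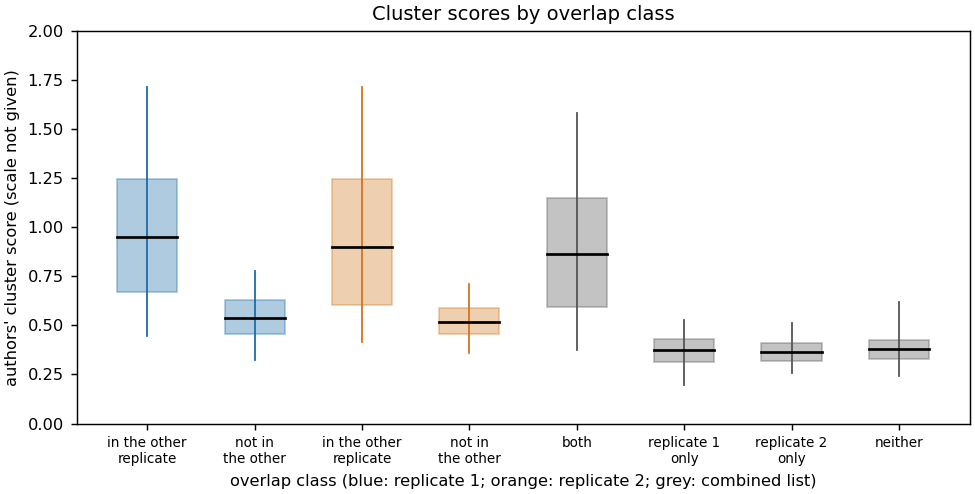
Scores of clusters (y axis, the authors' score, whose scale is not given) by overlap class (x axis); boxes span the 25th to 75th percentiles, lines the 5th to 95th, and black bars mark medians. In each replicate the clusters shared with the other replicate reach higher scores, with medians of 0.950 and 0.902 against 0.539 and 0.516, and in the combined list the clusters overlapping both replicates have the highest median score.

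The combined list held 7145 clusters that covered 24.5 Mb, more than either replicate. Both replicates overlapped 3840 of them, which is 53.7% (Wilson 95% interval 52.6 to 54.9%), and these held 78.0% of the covered sequence. Replicate 1 alone overlapped 1110 clusters and replicate 2 alone 356. Neither replicate overlapped 1839 combined clusters, which is 25.7% (24.7 to 26.8%) of the clusters and 10.0% of the covered sequence. Their median width was 1237 bp, and 1067 of them were narrower than the narrowest replicate cluster. Among combined clusters of at least 1301 bp, a limit chosen after seeing the data, 12.97% overlapped neither replicate. In the other direction, 99.2% of replicate 1 clusters and 99.3% of replicate 2 clusters overlapped the combined list. The combined list is not independent of the replicates, so no test was made.

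Along the chromosomes, RPD3 clusters covered between 13.3% and 17.1% of each main arm on average. They covered a smaller share of chromosome 4, which is small and largely heterochromatic, and little of the separately assembled heterochromatin. The mean covered share was 17.1% ± 1.98 on 2R, 15.1% ± 1.95 on 3R, 14.1% ± 2.03 on X, 13.3% ± 1.73 on 3L and 13.3% ± 1.60 on 2L (SD, n = 2). Arm 2R had the highest share in both replicates, 18.5% and 15.7%, against 14.4% and 12.1% on 2L. Replicate 1 covered more than replicate 2 on each arm. The SDs hold this shift common to the arms, so they do not measure the spread of differences between arms. No test between arms was made with 2 samples. Chromosome 4 had a mean of 9.31% ± 1.16 (SD, n = 2), which was 0.64 times the share of the autosomal arms in both replicates. Its clusters were about as frequent as those of the autosomal arms, at 42.9 against 45.1 per Mb in replicate 1 and 38.5 against 41.2 in replicate 2. They were narrower, with medians of 1937 against 2585 bp in replicate 1 and 2025 against 2618 bp in replicate 2. The Het sequences of X, Y, 2 and 3 together had 0.752% ± 0.0541 and the unplaced sequence U had 0.342% ± 0.0139 (SD, n = 2), against 1.42% and 0.839% in the combined list. The 3 lists held no cluster on Uextra. How much of chromosome 4 and of the Het, U and Uextra sequences reads could be placed on is unknown from the lists. The low shares there therefore do not show that RPD3 was absent. X and the autosomal arms had nearly equal shares, with ratios of 0.977 and 0.951 in replicates 1 and 2. In the combined list chromosome 4 stood at 0.794 times the autosomal arms by covered sequence and at 1.21 times by number of clusters. In the higher-scoring 50% of that list the value by covered sequence fell to 0.465.

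**Figure D2:**
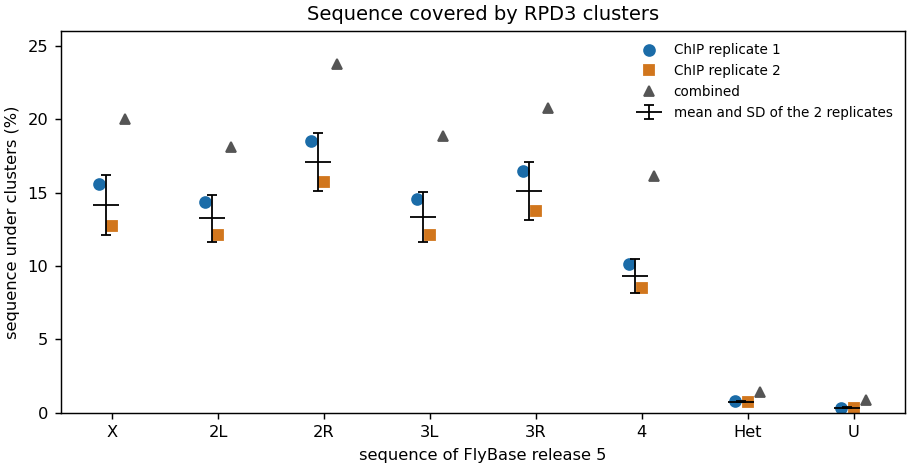
Share of each sequence under RPD3 clusters (y axis, percent) for the main arms, chromosome 4, the pooled Het sequences and U (x axis); coloured symbols are the 3 lists, and black bars give the mean and SD of the 2 replicates. The arms lie between 12.1% and 18.5% in the replicates, chromosome 4 at 10.1% and 8.49%, and Het and U below 1%, and the combined list lies above both replicates on each.

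In windows of 500 kb the 2 replicates traced the same profile of dense and sparse regions along the arms. Across 236 windows the covered shares had a Spearman's rho of 0.98 and a Pearson's r of 0.98 (permutation p = 1e-05 for rho), and neighbouring windows are not independent replicates. The window at 19.5 to 20.0 Mb of 2R was the densest, with 40.5% under clusters in replicate 1 and 34.8% in replicate 2, against medians over windows of 15.0% and 12.8%. The next densest in the combined list lay at 1.5 to 2.0 Mb of X, with 32.7% and 26.7%, and at 1.0 to 1.5 Mb of 3R, with 34.8% and 30.8%. The sparsest was the window at 24.0 to 24.5 Mb of 3L, at the centromere end of the arm, which held no replicate cluster. The part of this window on which reads could be placed is unknown from the lists. A sparse window also lay within an arm, at 10.0 to 10.5 Mb of 3L, where 1.06% and 1.32% were under clusters.

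**Figure D3:**
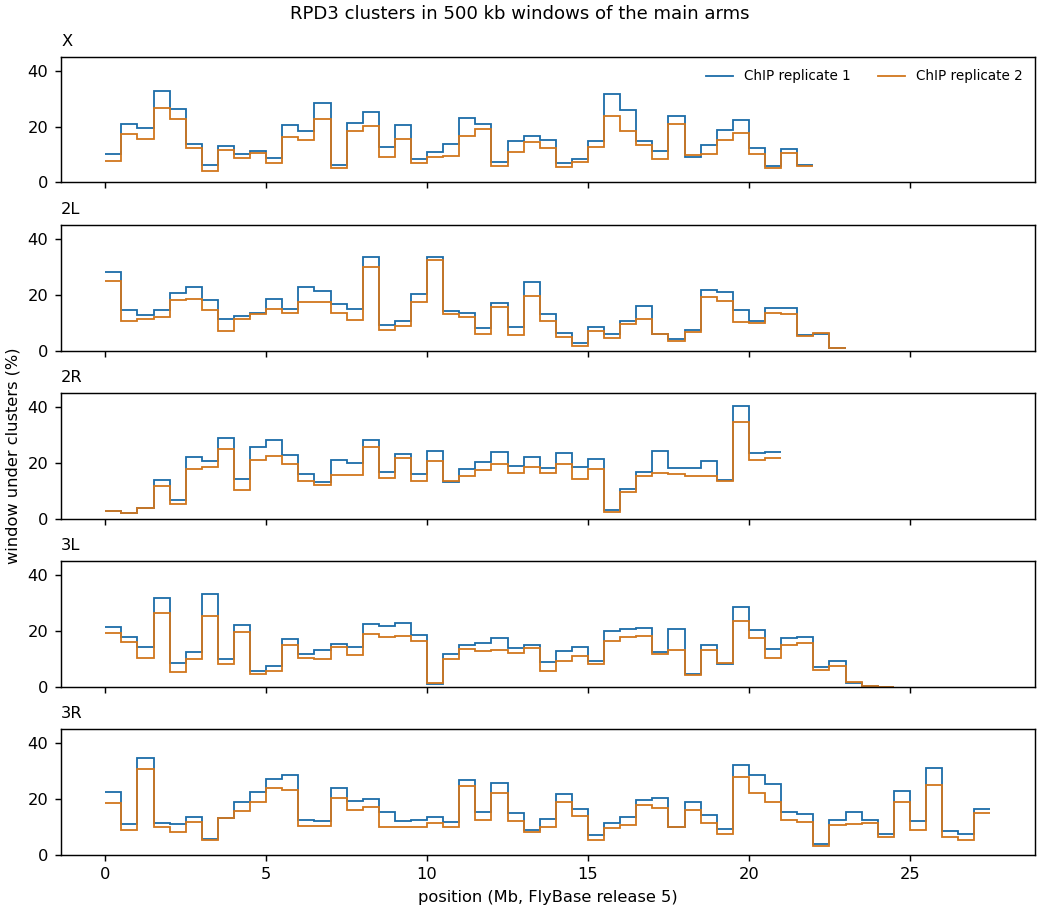
Share of each 500 kb window under RPD3 clusters (y axis, percent) along the 5 main arms (x axis, Mb of FlyBase release 5) for ChIP replicate 1 and ChIP replicate 2. The lines rise and fall together, with the highest window at 19.5 to 20.0 Mb of 2R and sparse windows at the high-coordinate end of 3L and the low-coordinate end of 2R.

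The same cluster had the top score in all 3 lists. It lay at 12519231 to 12521680 of 2L in the combined list, with scores of 3.79 in that list, 4.00 in replicate 1 and 3.57 in replicate 2. Among the 10 highest-scoring combined clusters that overlapped both replicates, 4 lay on 3R, 2 on X, 2 on U, 1 on 2L and 1 on 3L. The sequence U held 51 of the 7145 combined clusters, and whether reads from repeats raised the scores there was not tested. The 3R clusters were at 10956363 to 10958862 (score 2.80), 17443843 to 17446620 (2.40), 3634585 to 3637606 (2.38) and 19993780 to 19996660 (2.30). The X clusters were at 8291316 to 8294782 (2.62) and 11587583 to 11591047 (2.46), the 3L cluster at 18080133 to 18082439 (2.41), and those on U at 9710001 to 9712790 (2.92) and 7542039 to 7545897 (2.41). All 10 were between 2307 and 3859 bp wide, and each overlapped 1 cluster in each replicate. They ranked between 1 and 26 in the combined list, where clusters that did not overlap both replicates took ranks between them, including 5 narrow clusters with scores of 3.27 and 3.12 that neither replicate held.

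The widest RPD3 domains scored above the median of the combined list, 0.488, but below the highest-scoring clusters. The widest combined cluster spanned 33775 bp at 7032835 to 7066609 of 3R with a score of 1.16, and 2 clusters of replicate 1 and 3 of replicate 2 covered 91.7% and 90.9% of it. The others lay at 8230855 to 8261463 and 11028893 to 11057002 of 3R, 1751090 to 1779951 of X and 5454471 to 5483074 of 2R, with widths from 28110 to 30609 bp and scores of at most 1.24. Each of the 5 overlapped between 2 and 7 clusters in each replicate.

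Few high-scoring clusters were found in 1 replicate alone. In replicate 1 the highest of these were at 21463512 to 21465136 of 2L (score 1.58), 15682477 to 15684484 of 2L (1.15) and 20084316 to 20086429 of 3R (1.13). In replicate 2 they were at 17128640 to 17130058 of 3R (2.18), 67953 to 69472 of 3RHet (2.08) and 954103 to 955559 of 3LHet (1.82). These 3 clusters of replicate 2 were between 1419 and 1520 bp wide, close to the minimum width.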

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

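Alternatives chosen after the data were seen were the local shifts, the minimum width of 1301 bp, the arms without the 2 Mb next to the centromere, those for scores on X, merging for spacing, and single replicates for numbers, widths, covered length and spacing. The planned tests at gene starts, in annotated features, gene lists and motifs, and all their alternatives, were not run, since no annotation of release 5 was used here. No paired analysis was possible because the Input samples have no list of their own. The replicate overlap stayed past the threshold under each setting run, between 75.9% and 82.7% of replicate 1 and between 89.8% and 95.2% of replicate 2, and with local shifts chance rose to 26.5% and 29.6%. The rank correlation and the score differences of shared clusters also stayed past it with an overlap of at least 50%. In the higher-scoring 50% of each list the numbers were 3573 clusters in the combined list, 2748 in replicate 1 and 2496 in replicate 2, the median widths 3988, 3915 and 3523 bp, and the covered lengths 18.1, 13.1 and 10.6 Mb. With clusters closer than 200 bp merged the median widths were 2393, 2636 and 2654 bp. The replicate lists used alone in place of the combined list gave 4991 to 5496 clusters, median widths of 2565 to 2607 bp and 16.0 to 19.1 Mb. The share of combined clusters in both replicates was 59.6% in the higher-scoring 50% of the lists, and 64.5% were in both and 12.97% in neither for clusters of at least 1301 bp. Relative to the autosomal arms, by number of clusters the combined list gave 1.01 for X, 1.21 for 4, 0.130 for Het and 0.0874 for U, and in its higher-scoring 50% 1.08, 0.465, 0.0459 and 0.0501 by covered length, where the whole list gave 0.987, 0.794, 0.0698 and 0.0413. The replicates alone gave 0.951 to 0.977 for X, 0.635 to 0.636 for 4, 0.0496 to 0.0534 for Het and 0.0221 to 0.0249 for U. Without the 2 Mb next to the centromere the value for 4 was 0.764. By number chromosome 4 thus lay above the arms in the combined list, while in the replicates it lay below them, at 42.9 against 45.1 and 38.5 against 41.2 per Mb. The higher-scoring 50% holds fewer clusters by construction, and the cause of the other shifts was not tested. The median score on X no longer differed past the threshold in the higher-scoring 50% of the combined list, at 0.00464 (permutation p = 0.798), but did in those of the replicates, at 0.086 and 0.113, and the combined list kept differences of 0.159 and 0.148 at its 75th and 95th percentiles. Unknown read depth limits what the absence of a cluster means.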

Other observations

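Tests chosen only after their results or the data behind them were seen were those of cluster spacing and the centromere ends, the medians and densities of scores on X, the ratio of densities between score percentiles, both offsets of scores on X, exactly tied scores and the minimum width.

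RPD3 clusters lay closer together than random placement on the same arms would put them. In the combined list 37.4% of the gaps between neighbouring clusters were under 2000 bp, against 13.7% on average and 14.8% at most in 1000 random placements (one-sided permutation p = 0.001, the smallest they can give). The values were 30.8% against 10.3% in replicate 1 and 28.3% against 9.17% in replicate 2. Some neighbouring replicate clusters lay within 1 combined cluster, and with clusters closer than 200 bp merged the shares were 32.0% against 12.7% in the combined list, 27.0% against 9.81% in replicate 1 and 24.9% against 8.76% in replicate 2 (one-sided permutation p = 0.001 for each). Pieces of 1 domain that lie farther apart were not merged. The random placements did not keep the uneven density along the arms, where combined clusters covered from 0.715% to 51.8% of 500 kb windows. Uneven density alone would raise the share of short gaps, so the comparison does not separate it from closeness within a region. Clusters were sparser in the 2 Mb next to the centromere than on the rest of the arm on X, 2L, 2R and 3L, but not on 3R. In replicate 1 this stretch was 6.44% covered on X, 6.95% on 2L, 5.63% on 2R and 2.81% on 3L, against 16.5%, 15.1%, 19.9% and 15.6% on the rest of each arm. On 3R it was 20.0% against 16.2% in replicate 1 and 17.1% against 13.5% in replicate 2. The lists do not tell how much of these stretches reads could be placed on, so low shares there do not show that RPD3 was absent.

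Clusters on X scored higher than clusters on the autosomal arms, although X had about as many clusters per Mb. The median score on X was 0.916 against 0.779 in replicate 1 and 1.00 against 0.828 in replicate 2, differences of 0.137 (95% interval from resampled 500 kb windows 0.103 to 0.186) and 0.172 (0.110 to 0.230), and in both replicates X had the highest median of the 5 arms. At or above the 90th percentile of scores, X had 7.54 clusters per Mb against 3.83 on the autosomal arms in replicate 1 and 6.82 against 3.49 in replicate 2. These are ratios of 1.97 (1.58 to 2.41) and 1.96 (1.53 to 2.43), where all clusters gave 1.02 (0.868 to 1.17) and 0.994 (0.853 to 1.14). In the combined list the difference of medians was 0.0889 (0.0719 to 0.1196), and among its higher-scoring 50% it was 0.00464 (permutation p = 0.798), against 0.086 and 0.113 in the replicates (permutation p = 0.0001 for each, the smallest the resamples can give). At the 75th and 95th percentiles of the combined list X still exceeded the autosomal arms, by 0.159 (0.096 to 0.191) and 0.148 (0.091 to 0.219), and at or above the 90th percentile its ratio of clusters per Mb was 1.69 (1.37 to 2.03).

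A higher score needed to call a cluster on X was first tested by the 95th percentile of scores, by a test chosen before its result was seen, where X exceeded the autosomal arms by 0.240 (0.159 to 0.326) in replicate 1 and 0.211 (0.143 to 0.274) in replicate 2, which decides nothing since leaving out low-scoring clusters raises every percentile. It is argued against by the ratio of densities, chosen after densities above several scores had been looked at, which would stay level above a common score but rose 1.59-fold (1.35 to 1.85) and 1.60-fold (1.35 to 1.88) from the median to the 90th percentile. A different width of X clusters is also argued against, since within width deciles the difference was 0.133 in replicate 1 and 0.129 (0.0954 to 0.188) in replicate 2, and so is a constant offset added to the scores of called X clusters, since the difference at the 95th percentile exceeded that at the 5th by 0.140 (0.0529 to 0.230) in replicate 1 and 0.130 (0.0598 to 0.203) in replicate 2. A difference that grows with percentile would also come from a factor that multiplied the scores on X. At the 5th percentile the scores on X and the autosomal arms were 0.494 and 0.394 in replicate 1 and 0.476 and 0.395 in replicate 2. At the 95th they were 1.82 and 1.58 in replicate 1 and 1.85 and 1.64 in replicate 2. Whether 1 factor would give the differences at both percentiles was not tested, so a factor stays open. An offset that also acted on which clusters were called might come from how the score treats the copy number of X. It stays open too, because a lower limit on called scores would shrink the difference among low scores. From the 75th to the 95th percentile the rise was 0.0713 (0.00194 to 0.148, or -0.00729 to 0.151 with all windows resampled together) in replicate 1 and 0.0149 (-0.047 to 0.0784) in replicate 2, the labels do not state the sex of the larvae, and no biological explanation was tested.

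Most of the ranks from 1 to 26 in the combined list belonged to clusters that neither replicate held. Of the 715 combined clusters at or above the 90th percentile of scores, 34 overlapped neither replicate, among them those at 6907395 to 6908420 of 2R and 20037006 to 20038006 of 3R, both with a score of 3.27 and both named after their values were seen. The lower minimum width of the combined list may account for most of their absence from the replicate lists, as 91.2% (exact 95% interval 76.3 to 98.1%) were narrower than the narrowest replicate cluster. Scores formed from few reads are a candidate explanation of their height, since 52.9% (35.1 to 70.2%) had exactly the score of another cluster, against 0.735% of the 680 such clusters in both replicates (Fisher's exact test, one-sided, p = 2e-22), although 1150 clusters of the whole combined list shared a score. Reads from repeats may contribute too, since 64.7% (46.5 to 80.3%) lay on Het sequences, U, 4 or the 2 Mb next to a centromere, against 5.15% (Fisher's exact test, one-sided, p = 3e-18). The 34 clusters had a median width of 1003 bp, against 4685 bp for the 680. Of the 34, 31 were narrower than 1301 bp, and of the 680, 0 were. The comparisons of tied scores and of position therefore do not separate few reads or repeats from width. No biological explanation was tested.

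Replicate 1 covered 1.20 times as much sequence as replicate 2. Wider boundaries at the same places may account for part of this, as the median log2 width ratio of 1 to 1 pairs was 0.057 (95% interval 0.047 to 0.065) and 63.7% of the pairs were wider in replicate 1. These pairs made up 33.5% of the difference of 3.16 Mb, and clusters found in 1 replicate alone made up 52.0%. Read depth and the calling threshold were not tested, and no biological explanation was tested.

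The 1 region that the combined list named as depleted lay at 12734252 to 12735833 of 3L, with a score of -0.017. Replicate 1 had no cluster there, and replicate 2 had an enriched cluster at 12734238 to 12735839, whose score of 0.144 was the lowest in its list.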
